A study of Mus musculus with 6 samples.

How the data were processed

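Gene expression was measured by bulk RNA sequencing in 6 libraries of mouse esophageal organoids, 2 for each of 3 treatments. Per the labels, the RNA was extracted with an E.Z.N.A. kit, libraries were made with the Ovation Solo kit and sequenced on a NovaSeq instrument. The submitters name STAR 2.5.3a for alignment to GRCm38/mm10 and HTSeq for counting. They also name Cell Ranger 3.1.0, and the submitters name edgeR, both without stating what each was used for. Replicates were not pooled.

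The authors deposited a single table of 52636 genes. Its first set of columns holds a signal per library that the authors had scaled, each library to about the same total (20010331 to 20013923), and rounded up to whole numbers, so these values are not raw counts. A second set of deposited columns holds CPM (counts scaled to a fixed library total), each equal to the scaled value over its column total. The deposited table further holds the authors' log2 fold changes of each ligand treatment over the inhibitor group, and the authors' p-value and adjusted p-value, of which there is 1 per gene with no comparison named. Because the scaled values of a library fall on a regular grid, the number of reads behind each value was recovered, with every value within 0.212 of a whole read. The recovery was checked on simulated data, where 100% of values came back. Recovered reads were used for depths, counting floors and intervals, and for 1 alternative test, and not for the main test. Gene locations come from GENCODE vM21 on GRCm38, to which 52403 genes were matched by gene identifier.

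Samples were grouped by treatment as labelled. Replicate numbers were not in the model fixed in advance, and the labels do not say that equal numbers share a culture. Deviations of libraries of equal number correlated at 0.19, 0.174 and 0.258 in the 3 pairs of groups, so the numbers may pair the libraries, which these values do not settle. The main fit stayed without a block, as fixed in advance. The value with the replicate number as a block is given where it changed a call. Genes were kept when at least 2 of the 6 libraries reached 1 CPM, which left 18241. The deposited CPM were divided by trimmed-mean (TMM) factors, computed with trims of 30% and 5%, and log2 values were taken after adding 1. One limma model (version 3.58.1, R 4.3.3) with a term per group was fitted over all 6 libraries, with 3 residual degrees of freedom, a mean-variance trend and moderated variances. Comparisons were 2-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested with a threshold of 0.05. A change in this text is a log2 fold change of TMM-scaled CPM with its moderated standard error (SE), while group means are of CPM as deposited, with the SD of n = 2 libraries. Count-based testing had been planned for raw counts, and the stated fallback for normalized values, limma on log2(value+1), was used.

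Before the data were examined, the comparisons, the tests, the thresholds, 23 gene lists and the rule for naming genes were fixed. The rule names, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold whose libraries did not overlap between groups and whose higher group had a mean of at least 5 CPM, leaving out models without a usual symbol. It also names up to 4 members per list with the smallest adjusted p, 13 fixed genes, and the 10 opposed genes with the largest smaller change. Other list members are named as examples chosen after their values were seen. The lists cover targets of TGFb (SMAD2/3), BMP (SMAD1/5), Hedgehog, Wnt, Notch, p53 and NRF2, basal keratinocytes, squamous differentiation, columnar epithelium, mesenchymal transition, the cell cycle, prostaglandins and eicosanoids, inflammation and NF-kB, interferon response, PPAR and fatty acid oxidation, the integrated stress and unfolded protein response, cholesterol biosynthesis, and markers of fibroblasts, immune cells, endothelium, muscle, and Schwann and glial cells. A pair of genes is shared between the TGFb and BMP lists, and another pair between the TGFb and mesenchymal lists. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all lists and comparisons together. Lists with fewer than 3 tested members were not tested, which left 22 per comparison. The correlation estimated per list and fry were alternatives. Genes opposed by ibuprofen were those past the threshold in both steps with opposite signs. Since the TGFb1+BMP4 libraries enter both steps, their number is given beside that for independent lists and for 20 simulations of unchanged groups.

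The depth was 6413873 to 7730582 recovered reads per library. A group with no read of a gene was set to 3 reads over the group for a lower bound on the fold, and with 1 to 3 reads the ratio of depth-scaled reads is given with an exact 95% interval. Sequenced PCR copies are not independent molecules, so these floors and intervals cover counting error only. Simulated data had the same group sizes, 200 changed genes among 17966 tested and a dispersion of 0.02 for every gene. There, 47.8% and 50.2% of genes changed 2-fold were called in the first and second comparison. Of those changed 4-fold, 85.2% and 86.2% were called, while 3.9% and 4.9% of calls were false. Far more genes passed in the measured data, and their spread was not set to a single value, so these rates need not hold there.

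Alternatives were RLE and upper-quartile factors, no filter, a minimum of 5 CPM, a pseudocount of 0.1, a 2-fold threshold, only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. An omission leaves a group with a single library, which is then assumed to vary like the others. Chosen after seeing the data were a fit without TMM factors and limma-voom on the recovered reads. Rules for outlying samples and for other splits of the samples need larger groups and were not applied. Figures were drawn with matplotlib 3.10.9.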

Results

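Transcripts were measured in organoids, small epithelial cultures grown in a gel, from the esophagus of K5:Smo mice. In these mice tamoxifen turns on SmoM2, an always-active form of the Hedgehog signal transducer Smoothened, in cells that express the basal keratin Krt5. Esophagi were taken 5 days after tamoxifen, and organoids were cultured for 13 days. Treatments lasted 72 h and were renewed every 24 h. The first group received the TGFb receptor inhibitor A8301 at 500 nM, the second TGFb1 at 1 ng/ml with BMP4 at 20 ng/ml, and the third both ligands with 500 µM ibuprofen, which inhibits the prostaglandin-forming cyclooxygenases. Each group had 2 libraries. Their depth, as recovered from the deposited values, was 7307043 and 7730582 reads with the inhibitor, 6977533 and 6904541 with TGFb1+BMP4, and 6924160 and 6413873 with ibuprofen added. Whether the 2 libraries of a group came from separate cultures or animals is not stated, so they may be technical, and p-values here measure only the spread between these libraries. Nor do the labels say whether the inhibitor remained in the ligand groups. A count of 3 reads over a group, the floor used for bounds, equals 0.199, 0.216 and 0.225 CPM in the same order.

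Read composition differed between groups. Ribosomal protein genes took 2.60% ± 0.14 of reads with the inhibitor, 1.31% ± 0.01 with TGFb1+BMP4 and 1.80% ± 0.10 with ibuprofen added (SD, n = 2). The nuclear RNAs Malat1 and Neat1 together took 1.65% ± 0.13, 2.92% ± 0.08 and 3.32% ± 0.01, and mitochondrially encoded genes 2.65% ± 0.03, 2.33% ± 0.16 and 2.04% ± 0.25. Within each group, log2 CPM of the 2 libraries correlated across genes at 0.993 to 0.995, and genes are not independent replicates. Counts differed between the 2 libraries by more than counting error alone, with a chi-square per degree of freedom of 4.62, 7.48 and 6.46.

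The first comparison asks what TGFb1 and BMP4 change in this epithelium relative to a blocked TGFb receptor. No group lacked both the inhibitor and the ligands. Effects of TGFb1, of BMP4 and of the absence of the inhibitor therefore cannot be told apart, and ligand changes in this text mean all of them together. With the ligands, most TGFb targets (22 of 24), BMP targets (14 of 15) and mesenchymal transition genes (17 of 20) rose, while most genes of squamous differentiation (15 of 24), the cell cycle (19 of 27) and the integrated stress response (15 of 17) fell. Pmepa1, a feedback inhibitor of TGFb signalling, rose by 5.37 on the log2 scale, from 8.02 CPM ± 1.66 to 368 CPM ± 33.3 (SE 0.14, limma adjusted p = 2.98e-07). Id3, a helix-loop-helix repressor induced by BMP, rose by 2.16 (SE 0.16, adjusted p = 2.5e-05). Of 20 columnar genes 11 rose, such as the transcription factor Sox9 (2.56), and 2 fell, while the esophageal suprabasal keratin Krt13 fell by 1.46 from 8700 CPM ± 890 to 3170 CPM ± 585 (adjusted p = 0.00246). Of 18241 genes tested, 7354 (40.3%) passed the threshold, 3727 higher and 3627 lower, and 1735 and 1351 of these changed at least 2-fold. The 2 groups did not overlap for 72.2% of genes, against 33.3% by chance. Without TGFb inhibitor replicate 1 or 2 the count was 4713 or 4781.

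Among the 10 largest rises, Amtn, which encodes the enamel and junctional epithelium protein amelotin (chromosome 5, 88376108 to 88385916), went from 1 read to 13256, a ratio of 14400 with a 95% interval of 2580 to 567000. Its neighbour Odam, of the same protein group, had no read with the inhibitor and was at least 1710-fold higher. Elastin, Eln, was at least 359-fold higher. The stem cell receptor Lgr6 went from 1 read to 4937, a ratio of 5350 with an interval of 959 to 211000. The metalloprotease Adam12, the microtubule regulator Stmn2, C1qtnf3, Mill1, the platelet chemokine Ppbp and the basement membrane collagen Col4a3 rose by 6.32 to 7.25. The largest falls were of Serpinb12 (−7.82), the chitinase-like Chil1 (−6.04), Ptprz1, the defensin Defb3, Tmigd1, Stc2, Slc4a11, Acox2 and Sprr2i (−4.60), while the chemokine Ccl20 was at least 270-fold lower. With any 1 library of these groups left out, the bounds and ratios of reads stayed at or above 2330 for Amtn, 833 for Odam, 174 for Eln, 866 for Lgr6 and 115 for Ccl20, each lowest without TGFb inhibitor replicate 2. Sprr2i belongs to a family of closely related genes, and the labels do not say how reads shared between such genes were counted.

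**Figure D1:**
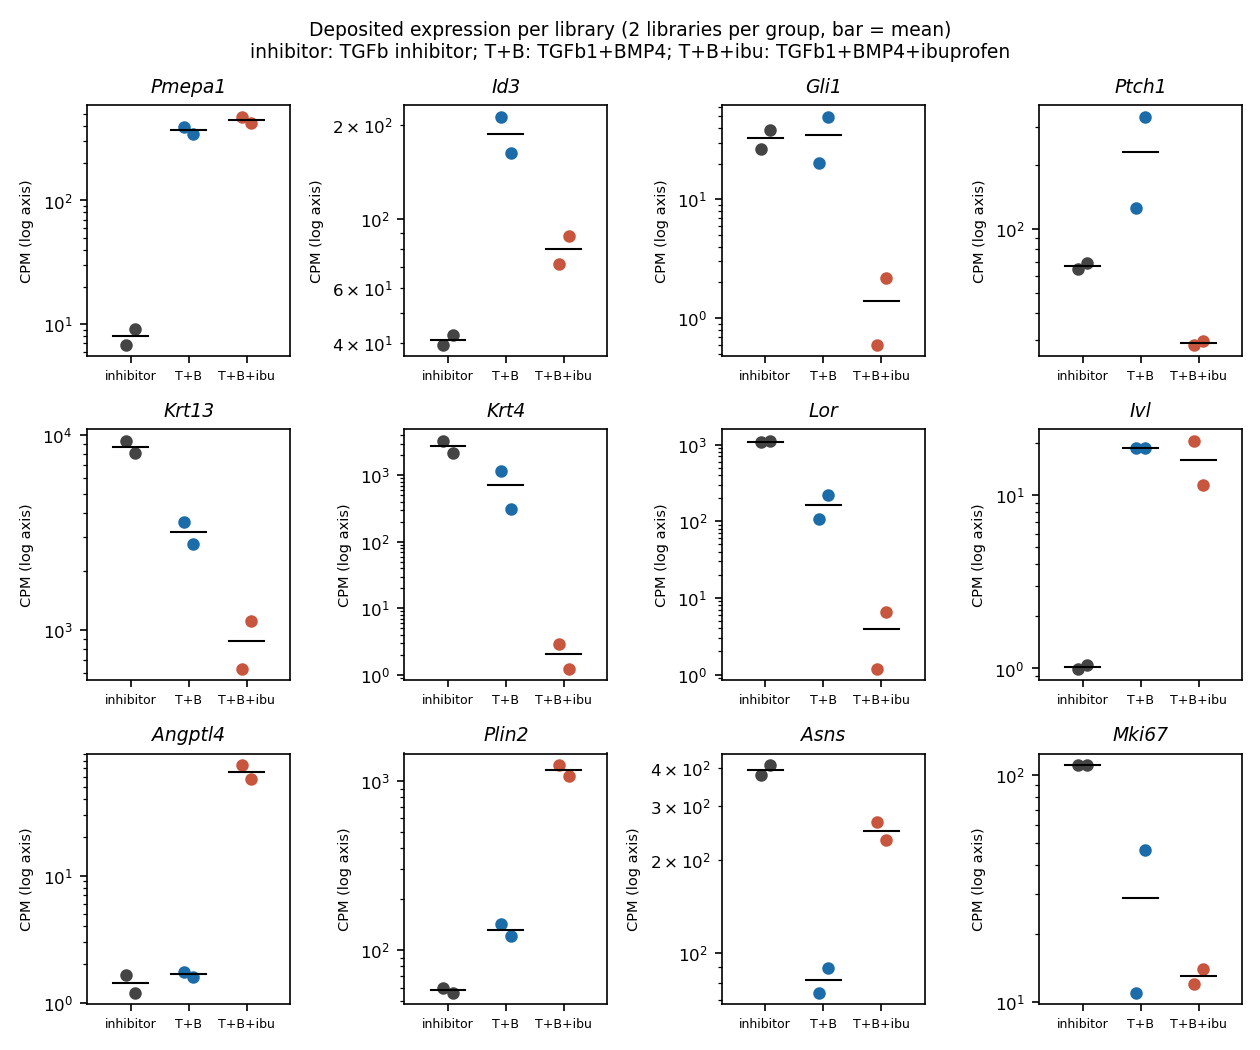
CPM as deposited (log axis) for 12 genes in each of the 6 libraries, with a bar at the mean of each group. Pmepa1 had a mean of 8.02, 368 and 450 CPM in the 3 groups, while Krt4 had 2730, 728 and 2.07 CPM; the TGFb1+BMP4 libraries stood apart from each other for Gli1, Ptch1, Krt4 and Mki67.

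Targets of both ligands moved up as sets. Of 24 TGFb targets, 22 rose and 1 fell, as many as adjusted over the list alone, with a median of 2.49 (camera, adjusted p = 5.86e-14; adjusted p = 0.179 with an estimated correlation). Pmepa1 rose by 5.37, Tgfbi by 4.14 and Smad7 by 2.20, Tsc22d1 fell by 0.56, and Snai2 did not pass (adjusted p = 0.131), except without TGFb1+BMP4 replicate 2 (0.0353). Of 15 BMP targets, 14 rose and none fell, also over the list alone, with a median of 2.16 (adjusted p = 3.05e-08; adjusted p = 0.179 with an estimated correlation), including Id1 (1.17), Id2 (3.17), Smad6 (2.26) and the antagonist Grem1 (3.28). Among 20 mesenchymal transition genes, 17 rose and none fell, over the list alone too, at a median of 2.12 (adjusted p = 1.15e-10; adjusted p = 0.624 with an estimated correlation), such as Vim (2.64), Zeb1 (2.02) and the collagen cross-linking enzyme Lox (4.92). Snai2, Twist1 and Tagln did not pass. Fibroblast markers rose in 13 of 14 genes, the same number adjusted over the list alone, with a median of 2.11, or 2.57 with genes unread in a group at their bound (adjusted p = 8.56e-07; adjusted p = 0.624 with an estimated correlation). Col1a1 rose by 5.79 and Postn by 5.54, and Fbln1 fell by 1.68. Dcn, at 0.92 (adjusted p = 0.0182), was not past the threshold without TGFb inhibitor replicate 1 (0.59, adjusted p = 0.123) or TGFb1+BMP4 replicate 2 (0.58, adjusted p = 0.0859) or with no filter (0.0691). Muscle markers rose in 3 of 8, again over the list alone (Des, Acta1, Ttn), with a median of 0.73 (adjusted p = 0.0269; adjusted p = 0.692 with an estimated correlation). That call ended without TGFb inhibitor replicate 1 (adjusted p = 0.0556) and without TGFb1+BMP4 replicate 2 (median 0.47, adjusted p = 0.0967), and Des rose by 0.73 rather than 1.12 without the former.

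Epithelial identity genes moved both ways. Of 24 squamous differentiation genes, 15 fell and 5 rose, or 16 and 5 adjusted over the list alone, at a median of −0.82 (adjusted p = 0.0137; adjusted p = 0.752 with an estimated correlation). The envelope protein Lor fell by 2.81, with Krtdap at −4.54, whereas the envelope precursor Ivl rose by 3.28 and the desmosomal cadherin Dsg1a by 3.47. Krt4 fell by 2.15 (adjusted p = 0.0126) to 728 CPM ± 589, by 1.18 without TGFb1+BMP4 replicate 2, and was not past the threshold without TGFb inhibitor replicate 1 (0.0798) or with no filter (0.0572). Columnar epithelium genes rose in 11 of 20 and fell in 2, or 12 and 2 adjusted over the list alone, at a median of 1.18 (adjusted p = 0.00869; adjusted p = 0.635 with an estimated correlation). The simple-epithelial keratins Krt7 (2.95, from 6.02 CPM ± 3.92 to 57.8 CPM ± 44.5) and Krt8 (2.66, from 0.675 CPM ± 0.0354 to 10.2 CPM ± 5.02) rose from low levels. Another 17 members of that list of 37, such as Tff1 and Cdx2, did not reach the filter. Basal keratinocyte genes rose in 7 of 14 and fell in 4, the same over the list alone, without a call (adjusted p = 0.332). Krt5 rose by 0.86 and Krt14 by 1.66, but Krt15 fell by 2.32 and Itga3 by 2.11.

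Growth and biosynthesis genes were mostly lower. Of 27 cell cycle genes 19 fell and 2 rose, or 20 and 2 adjusted over the list alone, at a median of −1.14 (adjusted p = 0.000285; adjusted p = 0.675 with an estimated correlation). The proliferation marker Mki67 fell by 2.21 and the mitotic activator Cdc20 by 2.67, whereas Rrm2 rose by 1.23. The TGFb1+BMP4 libraries differed for Mki67, at 11.04 and 46.62 CPM against a mean of 110 CPM ± 0.427 with the inhibitor, and it fell by 1.24 without TGFb1+BMP4 replicate 1. Integrated stress and unfolded protein response genes fell in 15 of 17 with none higher, also over the list alone, at a median of −1.11 (adjusted p = 2.18e-08; adjusted p = 0.624 with an estimated correlation). The transcription factor Atf4 fell by 1.18 and asparagine synthetase Asns by 2.26, with the serine synthesis enzyme Psat1 at −3.97. Cholesterol biosynthesis genes fell in 13 of 20 and rose in 1, or 14 and 2 adjusted over the list alone, at a median of −0.51 (adjusted p = 0.00027; adjusted p = 0.647 with an estimated correlation), with Lss down by 0.89.

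Hedgehog targets were split. Ptch1 rose by 1.61 (adjusted p = 0.00635), or by 0.93 without TGFb1+BMP4 replicate 2, and Gli2 by 1.18, while Ccnd2 fell by 1.25. Gli1 was at 32.5 CPM ± 8.55 with the inhibitor and 34.8 CPM ± 20.6 with the ligands (adjusted p = 0.997), and its change took the other sign with RLE factors and without TGFb inhibitor replicate 2 or TGFb1+BMP4 replicate 1. As a list of 8, with 2 up and 2 down also over the list alone, Hedgehog targets gave no call (adjusted p = 0.589). Of the enzymes that ibuprofen inhibits, Ptgs1 did not pass (−0.04, adjusted p = 0.914), with a positive value without TGFb inhibitor replicate 2 (0.13) or TGFb1+BMP4 replicate 1 (0.326). Ptgs2 fell by 0.84 (adjusted p = 0.0352). That fall ended as a call without TGFb inhibitor replicate 2 (−0.38, adjusted p = 0.203), TGFb1+BMP4 replicate 1 (0.159) or either ibuprofen replicate (0.0522 and 0.0507), and was −1.30 without TGFb inhibitor replicate 1. Prostaglandin E synthase, Ptges, fell by 3.30. The prostaglandin and eicosanoid list, with 5 of 21 up and 8 down (5 and 9 adjusted over the list alone), gave no call (adjusted p = 0.211).

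The remaining lists gave no call in this comparison. Inflammatory genes rose in 7 and fell in 8 of 23, over the list alone too (adjusted p = 0.907), with Cxcl5 up by 4.61 and Lcn2 down by 3.47. Interferon genes rose in 3 and fell in 1 of 8, or 5 and 1 adjusted over the list alone (adjusted p = 0.184), PPAR and fatty acid oxidation genes in 7 and 4 of 22 (adjusted p = 0.4) and NRF2 genes in 4 and 6 of 17 (adjusted p = 0.58). For p53 targets the counts were 4 and 5 of 16 (adjusted p = 0.292), for Wnt targets 4 and 1 of 9 (adjusted p = 0.291) and for Notch targets 4 and 4 of 9 (adjusted p = 0.929). Over their own lists alone only the NRF2 count of these changed, to 7 lower. Immune markers rose in 3 and fell in 1 of 7 (adjusted p = 0.413), with Itgam up by 1.80 and Cd68 down by 2.51, and 4 rose adjusted over the list alone. Endothelial markers rose in 2 and fell in 1 of 5, also over the list alone (adjusted p = 0.328), with Eng up by 2.40 and Esam down by 1.20. Only 2 of the Schwann and glial markers were expressed, too few for a test, and Mbp did not pass (adjusted p = 0.865). Altogether 10 of 22 lists were called, 6 up and 4 down. With correlations estimated from 6 libraries camera called 0, with 2 at an unadjusted p under 0.05 and a smallest adjusted p of 0.179, while fry, which tests whether a list moves without comparing it with other genes, called 9. Fry did not call the squamous (adjusted p = 0.136), cell cycle (0.0969) and muscle (0.136) lists, and it added the basal (0.00227) and Notch (0.018) lists. Median, mean and test differed in sign for 2 lists, none of them called.

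The second comparison asks what ibuprofen changes when the ligands are present. Most genes of PPAR and fatty acid oxidation (16 of 22) and cholesterol biosynthesis (16 of 20) rose with ibuprofen, while 4 of 8 Hedgehog targets, 7 of 15 BMP targets and 10 of 24 squamous differentiation genes fell. The lipase inhibitor Angptl4, a target of the fatty acid sensors PPAR, rose by 4.70 from 1.67 CPM ± 0.106 to 66.0 CPM ± 12.0 (SE 0.22, adjusted p = 2.37e-05), and the lipid droplet protein Plin2 rose as well. Gli1, the transcription factor that reports Hedgehog activity, fell by 3.80 from 34.8 CPM ± 20.6 to 1.40 CPM ± 1.13 (SE 0.43, adjusted p = 0.000721). In all, 3601 genes (19.7%) passed the threshold, 1957 higher and 1644 lower, or 519 and 737 with at least a 2-fold change. Without TMM factors the numbers were 1549 and 2037, a share higher of 43.2% in place of 54.3%, with the median of all genes at −0.07. Groups did not overlap for 58.8% of genes, against 33.3% by chance. The count dropped to 2261 without TGFb1+BMP4 replicate 2 and 1641 without ibuprofen replicate 1, and was 2356 with no filter.

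The pyruvate dehydrogenase kinase Pdk4 rose by 3.31. Erc2, Slc9a2, Sprr2i, the glycerol channel Aqp9, Dlgap1 and the chemokine Cxcl1 were among the other large rises, at 3.14 to 4.47. Among the falls, Odam had no read left and was at least 1520-fold lower. Amtn fell by 7.84 and the suprabasal keratin Krt4 by 7.60, from 728 CPM ± 589 to 2.07 CPM ± 1.17. The lipoxygenase Alox15 went from 2145 reads to 1, a ratio of 2060 with an interval of 370 to 81400, from libraries that differed within the TGFb1+BMP4 group (154 CPM ± 132). With any 1 library of these groups left out, the fold stayed at or above 731 for Odam (without ibuprofen replicate 1) and 357 for Alox15 (without ibuprofen replicate 2). Krt10, C1qtnf3, Dsg1a, Tgm7, the kallikrein Klk13 and the cornified envelope protein Rptn fell by between −6.53 and −5.41.

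PPAR and fatty acid oxidation genes rose in 16 of 22 and fell in 1, the same over the list alone, at a median of 1.00 (adjusted p = 1e-09; adjusted p = 0.256 with an estimated correlation). They included the carnitine transferase Cpt1a (1.06), Ucp2 (1.47) and Acot1 (2.32). Cholesterol biosynthesis genes rose in 16 of 20 with none lower, or 17 adjusted over the list alone, at a median of 0.71 (adjusted p = 6.75e-12; adjusted p = 0.558 with an estimated correlation), such as Lss (1.31) and Dhcr7 (1.34). Integrated stress and unfolded protein response genes rose in 11 of 17 with none lower, or 13 adjusted over the list alone, at a median of 0.69 (adjusted p = 6.44e-09; adjusted p = 0.624 with an estimated correlation), including Asns (1.67) and Trib3 (1.94). NRF2 genes rose in 8 of 17 and fell in 1, or 9 and 1 adjusted over the list alone, at a median of 0.41 (adjusted p = 0.00926; adjusted p = 0.624 with an estimated correlation). The cystine transporter Slc7a11 rose by 2.39 and Hmox1 by 0.94, Gclc fell by 0.88, and the call ended without ibuprofen replicate 2 (adjusted p = 0.167).

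Hedgehog targets fell in 4 of 8 and rose in 1, also over the list alone, at a median of −1.20 (adjusted p = 0.00926; adjusted p = 0.647 with an estimated correlation). That median was −1.93 without TGFb1+BMP4 replicate 1 and −0.62 without replicate 2, with the call kept, but fry did not call the list (adjusted p = 0.115). Ptch1, the Hedgehog receptor, fell by 2.70 to 29.1 CPM ± 0.809, Gli2 by 2.85 and Foxe1 by 1.41, while the cyclin Ccnd2 rose by 0.90. The Foxe1 fall was 0.91 without TGFb1+BMP4 replicate 2 and no call without ibuprofen replicate 1 (adjusted p = 0.0722). Fibroblast markers were lower too in 5 of 14 and higher in 1, without a call as a list (median −0.42, adjusted p = 0.059). Gli1 overlaps the gene Arhgap9 on the other strand, which lay at 1.25 CPM ± 0.283 with the ligands. BMP targets fell in 7 of 15 and rose in 1, the same over the list alone, at a median of −0.73 (adjusted p = 0.00197; adjusted p = 0.331 with an estimated correlation). Id3 fell by 1.14 and Bambi by 2.12. Id1 did not pass (−0.28, adjusted p = 0.173), except without ibuprofen replicate 2 (0.0433), and Smad7 rose by 0.45, no longer a call without TGFb1+BMP4 replicate 2 (0.125) or ibuprofen replicate 1 (0.0976) or 2 (0.0835). TGFb targets gave no call (adjusted p = 0.929), with 5 of 24 higher and 3 lower, the same over the list alone, among them Tgfbi (0.75) and Igfbp3 (−2.10). Wnt targets fell in 2 of 9 with none higher, or 5 adjusted over the list alone, at a median of −0.43 (adjusted p = 0.022; adjusted p = 0.673 with an estimated correlation). Tnfrsf19 fell by 1.44, on few reads, from 31 with the ligands to 2 with ibuprofen added, a ratio of reads of 14.9. The list's call ended without TGFb1+BMP4 replicate 2 and with a minimum of 5 CPM (camera adjusted p = 0.0716).

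Squamous differentiation genes fell in 10 of 24 with none higher, or 13 lower and 1 higher adjusted over the list alone, at a median of −0.43 (adjusted p = 1.99e-05; adjusted p = 0.647 with an estimated correlation). Besides Krt4 and Dsg1a, Lor fell by 5.19, the transglutaminase Tgm3 by 4.45 and Krt13 by 1.83, whereas Ivl and Tgm1 did not pass. Columnar genes gave no call (adjusted p = 0.877), with 4 of 20 higher and 3 lower (4 and 5 adjusted over the list alone). Epcam rose by 1.89 and Krt7 fell by 2.34 (adjusted p = 0.0264), a call that ended without TGFb1+BMP4 replicate 1 (−1.45, adjusted p = 0.098), ibuprofen replicate 1 (0.0556) or replicate 2 (0.137). Krt8 lay near the threshold (−1.32, adjusted p = 0.0514) and passed in several alternatives, such as without TGFb1+BMP4 replicate 2 (0.0237), without ibuprofen replicate 1 (0.0412), without TMM factors (0.0433) and with the replicate number as a block (0.0106). Sox9 did not pass (0.18, adjusted p = 0.191). Basal genes rose in 4 of 14 and fell in 1, or 5 and 2 adjusted over the list alone (adjusted p = 0.602), with Cd44 up by 0.94. Krt5 lay at the threshold (−0.38, adjusted p = 0.0502), and it passed without TMM factors (0.0162), with a pseudocount of 0.1 (0.0401), with a minimum of 5 CPM (0.0376) and with voom (0.0217).

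Ptgs2 rose by 1.63 (adjusted p = 0.00402) and Ptges by 3.09, the prostaglandin transporter Slco2a1 by 1.36 and the arachidonate-releasing phospholipase Pla2g4a by 1.07. Ptgs1 did not pass (0.50, adjusted p = 0.153), except without TGFb1+BMP4 replicate 2 (0.85, adjusted p = 0.0162). The prostaglandin and eicosanoid list, 6 of 21 higher and 4 lower, also over the list alone, gave no call (adjusted p = 0.577). Without a call there were also inflammatory genes with 8 higher and 4 lower of 23, or 9 and 4 adjusted over the list alone (adjusted p = 0.171), where Cxcl1 rose by 3.14 and the alarmin Il33 fell by 2.69. Interferon genes (adjusted p = 0.258), immune markers (0.929), endothelial markers (0.754), cell cycle genes (0.211), p53 targets (0.0523), Notch targets (0.114), mesenchymal genes (0.589), muscle markers (0.0672) and fibroblast markers (0.059) gave none either. Rises and falls in these were 1 and 1 of 8, 1 and 1 of 7, 0 and 0 of 5, 1 and 2 of 27, 5 and 1 of 16, 0 and 3 of 9, 3 and 3 of 20, 0 and 1 of 8 and 1 and 5 of 14. Adjusted over the list alone, 7 p53 targets rose, and 1 cell cycle gene and 6 fibroblast markers fell, the others being equal. Cd68 rose by 1.07, while Itgam fell by 1.47, Myh1 by 1.88 and Postn by 2.67. Of the glial markers only Mbp passed (0.48, adjusted p = 0.0405), not so without TGFb1+BMP4 replicate 2 (0.32, adjusted p = 0.205), TGFb inhibitor replicate 1 (0.0515) or ibuprofen replicate 1 (0.11) or 2 (0.154). Without TGFb1+BMP4 replicate 1, 14 rather than 8 lists were called, the cell cycle (0.000111), fibroblast (0.00159), muscle (0.00699), p53 (0.0259), inflammatory (0.0414) and mesenchymal (0.0414) lists being added. Without ibuprofen replicate 2 the muscle (0.00218), fibroblast (0.00673) and p53 (0.0475) lists passed, and without TGFb1+BMP4 replicate 2 the Notch list (0.0288). With the replicate number as a block the fibroblast (0.0178), muscle (0.0245) and p53 (0.0346) lists passed, as did fibroblast markers with a minimum of 5 CPM (0.0264) and p53 targets without TMM factors (0.0469). With estimated correlations camera called 0 of 22, 2 at an unadjusted p under 0.05 and a smallest adjusted p of 0.256, and fry called 6. The Hedgehog (fry adjusted p = 0.115), squamous (0.0726), NRF2 (0.0633) and Wnt (0.177) calls ended with fry, while the basal (0.0254) and Notch (0.00849) lists were added. Median, mean and test differed in sign for 4 lists, none called.

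**Figure D2:**
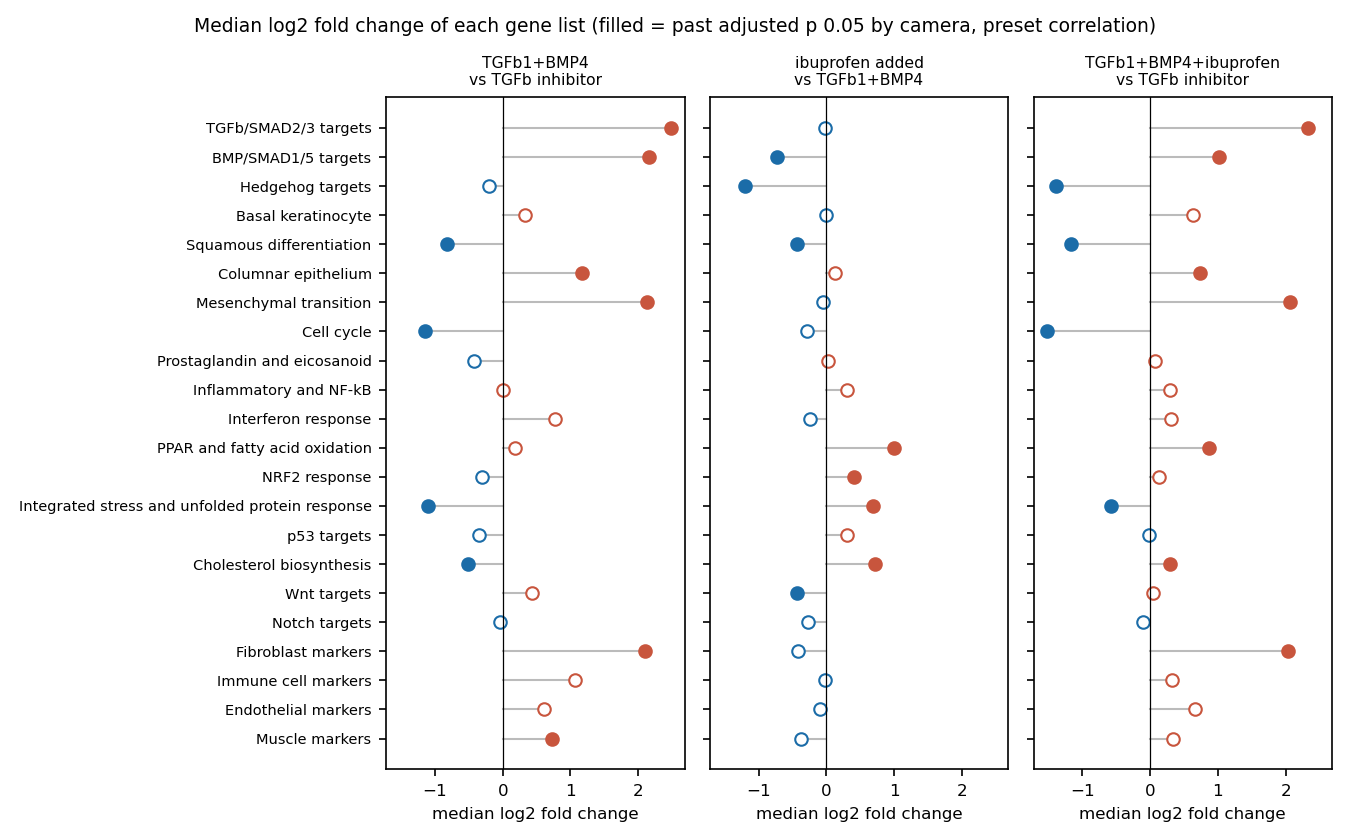
Median log2 fold change of each of the 22 tested gene lists (vertical axis) in the 3 comparisons (panels), with a line from 0 and filled points for lists past an adjusted p of 0.05 by camera at the preset correlation. TGFb targets had medians of 2.49, −0.02 and 2.33, Hedgehog targets −0.21, −1.20 and −1.38, and PPAR genes 0.19, 1.00 and 0.87.

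The third comparison sets ligands with ibuprofen against the inhibitor and shows which ligand changes were present with the drug. As with the ligands alone, most TGFb targets (22 of 24) and mesenchymal transition genes (16 of 20) rose and most squamous (19 of 24) and cell cycle genes (20 of 27) fell, and 7 of 8 Hedgehog targets fell as well. The cadherin Cdh6 rose by 7.80 and the lubricin gene Prg4 by 6.98, whereas Krt4 fell by 9.75 from 2730 CPM ± 806 to 2.07 CPM ± 1.17 (SE 0.53, adjusted p = 5.93e-06). There were 7419 genes (40.7%) past the threshold, 3791 higher and 3628 lower, or 1642 and 1433 changed at least 2-fold. Without TMM factors 3330 were higher and 4180 lower, a share higher of 44.3% in place of 51.1%, so the balance turned. Of all genes 72.4% had groups that did not overlap, against 33.3% by chance. The count was 4680 without TGFb inhibitor replicate 1 and 4912 without replicate 2. Adam12, Krt20, Stmn2, Timp1, the integrin Itgb3 and Pmepa1 rose by 5.73 to 7.64, and Cyp4a10, a fatty acid hydroxylase, was at least 363-fold higher. Timp1 and Prg4 overlap Syn1 and Tpr on the other strand. Serpinb12 went from 7897 reads to 1, a ratio of 7000 with an interval of 1260 to 277000, Serpinb3a was at least 1340-fold lower, and the claudin Cldn8 at least 497-fold lower. With any 1 library of these groups left out, the folds stayed at or above 177 for Cyp4a10 (without TGFb inhibitor replicate 2), 1210 for Serpinb12 (without ibuprofen replicate 2), and 643 and 239 for Serpinb3a and Cldn8 (without ibuprofen replicate 1). Lor, Tmprss11a, Hrnr, the desmocollin Dsc1, Klk13 and Krtdap fell by between −8.00 and −6.50.

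TGFb targets rose in 22 of 24 with none lower, also over the list alone, at a median of 2.33 (adjusted p = 6.05e-14; adjusted p = 0.179 with an estimated correlation), with Smad7 at 2.65 and Pmepa1 at 5.73. BMP targets rose in 11 of 15 and fell in 1, or 12 and 1 adjusted over the list alone, at a median of 1.02 (adjusted p = 7.03e-05; adjusted p = 0.256 with an estimated correlation). Id1 rose by 0.90, Id3 by 1.02 and Smad6 by 2.57. Mesenchymal genes rose in 16 of 20 with none lower, over the list alone too, at a median of 2.07 (adjusted p = 1.89e-09; adjusted p = 0.624 with an estimated correlation), with Vim at 2.31 and Lox at 4.51. Fibroblast markers rose in 12 of 14 and fell in 1, also over the list alone, at a median of 2.04, or 2.17 with bounds (adjusted p = 5.58e-06; adjusted p = 0.635 with an estimated correlation). Col1a1 rose by 5.22, and Fbln1 fell by 2.17. Columnar genes rose in 10 of 20 and fell in 1, the same over the list alone, at a median of 0.74 (adjusted p = 0.00926; adjusted p = 0.635 with an estimated correlation), which became 1.19 without TGFb inhibitor replicate 1, 0.24 without ibuprofen replicate 1 and 1.11 without ibuprofen replicate 2. Sox9 rose by 2.74 and Epcam by 3.00, and Spdef fell by 2.16. Krt8 rose by 1.34 (adjusted p = 0.0278), but did not pass without TGFb inhibitor replicate 1 (0.0989) or 2 (0.102) or ibuprofen replicate 1 (0.84, adjusted p = 0.172), and Krt7 did not pass (0.61, adjusted p = 0.448), except with the replicate number as a block (0.0357). PPAR genes rose in 17 of 22 and fell in 1, or 17 and 2 adjusted over the list alone, at a median of 0.87 (adjusted p = 6.8e-07; adjusted p = 0.3 with an estimated correlation), with Plin2 at 4.37.

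Cholesterol genes rose in 10 of 20 and fell in 3, also over the list alone, at a median of 0.29 (adjusted p = 0.0311; adjusted p = 0.752 with an estimated correlation), with Sc5d at 1.34. This call ended without TGFb inhibitor replicate 1 (adjusted p = 0.0639), without ibuprofen replicate 2 (median 0.18, adjusted p = 0.199), without TMM factors (0.0539) and with a minimum of 5 CPM (0.0582). Hedgehog targets fell in 7 of 8 with none higher, also over the list alone, at a median of −1.38 (adjusted p = 0.00149; adjusted p = 0.647 with an estimated correlation). Gli1 fell by 3.81 (SE 0.43, adjusted p = 0.000237) and Gli2 by 1.67. Ptch1 fell by 1.09 (adjusted p = 0.0335), with an adjusted p of 0.097 to 0.124 without any 1 of the inhibitor or ibuprofen replicates. Squamous genes fell in 19 of 24 and rose in 1, or 19 and 2 adjusted over the list alone, at a median of −1.17 (adjusted p = 8.56e-07; adjusted p = 0.635 with an estimated correlation). Krt13 fell by 3.29 and Tgm3 by 5.79, whereas Ivl rose by 3.08. Cell cycle genes fell in 20 of 27 and rose in 2, or 22 and 2 adjusted over the list alone, at a median of −1.52 (adjusted p = 2.08e-05; adjusted p = 0.647 with an estimated correlation), with Mki67 at −2.91 and Rrm2 at 1.58. Integrated stress genes fell in 10 of 17 and rose in 2, or 13 and 2 adjusted over the list alone, at a median of −0.58 (adjusted p = 0.00328; adjusted p = 0.647 with an estimated correlation), with Psat1 at −2.67.

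No call was made for basal keratinocyte (adjusted p = 0.128), prostaglandin and eicosanoid (0.788), inflammatory (0.58), interferon (0.58), NRF2 (0.332), p53 (0.845), Wnt (0.788), Notch (0.707), immune (0.589), endothelial (0.4) and muscle (0.575) lists. Rises and falls were 8 and 4 of 14, 6 and 8 of 21, 8 and 7 of 23, 2 and 0 of 8, 7 and 5 of 17, 4 and 5 of 16, 2 and 2 of 9, 3 and 4 of 9, 3 and 1 of 7, 2 and 1 of 5 and 3 and 1 of 8. Adjusted over the list alone, 9 basal, 7 prostaglandin and 9 inflammatory genes rose, and the other numbers were equal. Krt5 rose by 0.48 (adjusted p = 0.00998), not past the threshold without TGFb inhibitor replicate 1 (0.0907) or 2 (0.073). Cxcl3 rose by 5.02, S100a9 fell by 4.47, H2-Ab1 rose by 2.40 and Cd68 fell by 1.44. Ptges did not pass (−0.20, adjusted p = 0.388), nor did Ptgs1 (0.46, adjusted p = 0.13), except without TGFb1+BMP4 replicate 1 (0.0259) or 2 (0.0326) or with only the 2 groups compared (0.0275). Ptgs2 rose by 0.79 (adjusted p = 0.0442), a call that ended without TGFb inhibitor replicate 1 (0.32, adjusted p = 0.28) or ibuprofen replicate 1 (0.183) or 2 (0.0924), and was 1.24 without TGFb inhibitor replicate 2. Of the glial markers, Mbp rose by 0.45, but not without TGFb inhibitor replicate 2 (adjusted p = 0.201) or ibuprofen replicate 1 (0.0703) or 2 (0.129). Of 22 lists 11 were called, 7 up and 4 down; with estimated correlations camera called 0, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.179, and fry called 9. Lists called by camera and not by fry were Hedgehog (0.0555), cell cycle (0.0643), integrated stress (0.0502) and cholesterol (0.0897), and fry added basal (0.000981) and Notch (0.0354). Median, mean and test differed in sign for 4 lists, none called.

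A last question is which ligand changes ibuprofen opposed. Of the genes past the threshold with the ligands, 1680 (22.8%) also passed the other way with ibuprofen, 783 of them up and then down and 897 down and then up, while 549 went the same way in both steps. Independent lists of these sizes would share 725 opposed genes and 727 in the same direction. Simulated unchanged groups gave a mean of 0.2 opposed genes. With no gene changed, few pass in either step, so that number is no yardstick for 1680. Of the genes changed with the ligands, 66% had the opposite sign under ibuprofen, against 66.7% of all genes in the simulated groups. The simulated share covers all genes in groups without any change, while the measured share covers only genes that passed. These shares are not alike, so the signs alone cannot decide on an excess over shared noise. Because the TGFb1+BMP4 libraries enter both steps with opposite signs, their noise alone gives a negative relation, so part of the number over 725 may come from the shared libraries. The 2 log2 fold changes had a covariance of −0.17 across genes, against −0.03 in the simulated groups. Their correlation was −0.29, and shared noise alone gave −0.50 in the simulated groups, a value set by the shared libraries whatever the size of the noise. Against the inhibitor, 473 of the 783 and 503 of the 897 were not past the threshold with ligands and ibuprofen, 240 and 298 were still changed the same way, and 70 and 96 had changed the other way. The opposed number was 1106 without TGFb1+BMP4 replicate 1, 887 without ibuprofen replicate 1, and 498 at 2-fold in both steps. The 10 opposed genes with the largest changes were all up and then down. Odam had no read with the inhibitor or with ibuprofen, and 341 CPM ± 208 with the ligands alone. Amtn kept 3.47 CPM ± 3.07 with ibuprofen, still above the inhibitor group (ratio of reads 50.7, interval 8.65 to 2050, at least 8.22 without TGFb inhibitor replicate 2), with a log2 change of 1.90, or 1.13 without ibuprofen replicate 2. Krt10 and Krt42 lay at 1050 CPM ± 274 and 358 CPM ± 77.1 with the ligands and at 9.82 CPM ± 2.86 and 18.8 CPM ± 0.986 with ibuprofen added. The nitric oxide synthase Nos1, C1qtnf3, Alox15, the semaphorin Sema3d, Gabrp and the cysteine dioxygenase Cdo1 completed the set. Against the inhibitor, Krt10 fell by 1.34 (adjusted p = 0.0252), but by 2.05 without TGFb inhibitor replicate 1, 0.65 without replicate 2 (adjusted p = 0.104) and with an adjusted p of 0.146 without ibuprofen replicate 1, while Cdo1 fell by 0.74, ending without TGFb inhibitor replicate 2 (0.0901) or ibuprofen replicate 1 (0.0921). Alox15 and Sema3d were not past the threshold there, but passed in some alternatives, Alox15 for example without TGFb inhibitor replicate 2 (0.0201) and with the replicate number as a block (0.0455), and Sema3d without ibuprofen replicate 1 (0.0465) and with a pseudocount of 0.1 (0.0246).

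**Figure D3:**
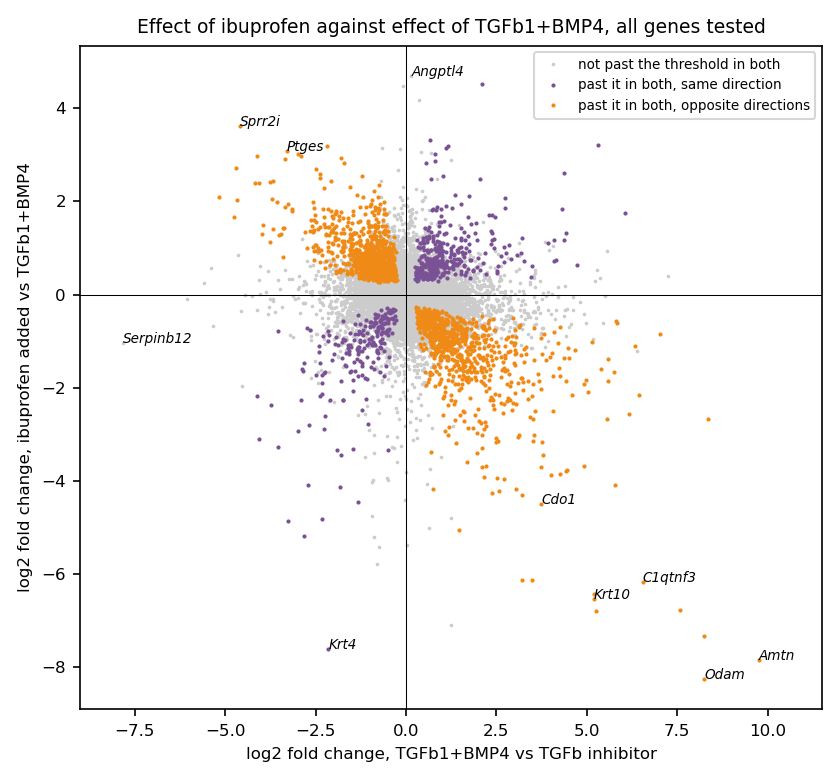
Log2 fold change with ibuprofen added (vertical axis) against log2 fold change with TGFb1+BMP4 (horizontal axis) for the 18241 genes tested, each point a gene, coloured by whether it passed the threshold in both steps. Opposed genes (1680) outnumber those that moved the same way (549), and the TGFb1+BMP4 libraries enter both axes.

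The authors' deposited table gives 1 adjusted p-value per gene, under 0.05 for 3495 genes. Limma-voom on the deposited scaled values with TMM factors, no filter and an F test over the 3 groups gave the same 3495 genes, with p-values within 1e-13, so that value covers any difference between the groups rather than a single comparison. Among the genes tested here, 2737 were under 0.05 in the authors' deposited table. Voom with the same F test on the recovered, filtered reads gave 8893 genes, and limma on log2 CPM gave 9121. The authors' deposited log2 fold changes correlated with those here across genes at 0.929 for the ligands and 0.924 for ligands with ibuprofen. Genes featured here did not all pass in the authors' F test. Its adjusted p was 0.269 for Gli1 and Krt4, 0.244 for Ptch1 and 0.284 for Odam. For Angptl4, Krt13 and Sox9 it was 0.0251, 0.0461 and 0.00339. That adjustment also covered 21171 genes with no read in any library. Of the 67 genes named by rank or in advance, 19 overlapped another gene with reads, and 3 of these a protein-coding one.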

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

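Fits without TMM factors and with voom on the recovered reads were chosen after the results were seen, the other alternatives before. Genes changed with the ligands, with ibuprofen added and with both against the inhibitor, 7354, 3601 and 7419, and the 1680 opposed genes kept within 1.5 times their number under RLE and upper-quartile factors, a minimum of 5 CPM, a pseudocount of 0.1, only the 2 groups compared, no TMM factors, voom and the replicate block (7964, 4338, 8017 and 2028). The replicate block called 10, 11 and 11 lists. Beyond the gains given beside the results, it changed no call of a list or of a gene named by the rule. With no filter the ibuprofen count was 2356, since 31465 genes were then adjusted for. With at least a 2-fold change the counts were 3086, 1256, 3075 and 498, since a stricter rule leaves fewer. Leaving out a library gave 4713 to 7324, 1641 to 2879, 4680 to 7544 and 887 to 1295, where fewer libraries remained. Called lists were 9 to 10, 8 to 14 and 10 to 11 without a library; with an estimated correlation they were 0 in each comparison and with fry 9, 6 and 9. The cause of the difference between these list tests was not tested.

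Among 342 values of named genes, 4875 refits kept sign and side of the threshold, 184 lost the call, 18 gained one and 8 changed sign. Gli1 with the ligands was 0.005 with RLE factors, 0.275 without TGFb inhibitor replicate 2 and 0.594 without TGFb1+BMP4 replicate 1, a range of −0.595 to 0.594 over omissions. Ptgs1 with the ligands was 0.13 and 0.326 without the same replicates (range −0.394 to 0.326). Gabrp with ligands and ibuprofen was −0.353 without TGFb inhibitor replicate 2 (range −0.353 to 0.608), and Odam, unread in both groups, was 0 with a pseudocount of 0.1 and 0.269 with voom. None of these 8 passed the threshold, and the cause was not tested. With voom, Alox15 with ibuprofen (adjusted p = 0.15) and, against the inhibitor, Hrnr (0.0771), Amtn (0.0905) and Krt10 (0.0775) did not pass. The 29 called lists kept direction and call in 299 refits and lost the call in 49, of which 29 with the estimated correlation and 11 with fry. The 37 lists without a call stayed so in 420 refits and gained one in 21. The alternative with DESeq2 was not run, because the deposited values are not raw counts. Nor was it run on the recovered reads, for which only voom was used. At this depth a gene unread in a group can lie anywhere up to 0.225 CPM.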

Other observations

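Families below were chosen after their values were seen. Of 75 ribosomal protein genes, 73 fell with TGFb1+BMP4 (median −0.95), 61 rose when ibuprofen was added (0.53) and 59 were lower in the ibuprofen group than with the inhibitor (−0.40). Aminoacyl-tRNA synthetase genes, which charge transfer RNA for translation, followed them, with 17 of 18 lower, 14 higher and 16 lower. Directions were the same under TMM, RLE and upper-quartile factors and without factors. Collagen genes rose in 27 of 33 with the ligands and fell in 2, then fell in 11 and rose in 3 with ibuprofen. Of 20 integrin genes, 14 rose and 3 fell with the ligands.

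Envelope gene families parted. Late cornified envelope genes (Lce), 19 in all, fell in 9 with the ligands and in 12 with ibuprofen, and 16 were lower with both, none being higher in any step. The falls with ibuprofen were all of Lce1 members, and no Lce3 member passed in that step. In contrast, 9 of 11 Sprr2 genes fell with the ligands, and with ibuprofen 5 rose and 1 fell. Mitochondrially encoded protein genes, 13 in number, had medians of −0.11, −0.12 and −0.46, with 0, 2 and 4 lower. All of these signs held under each scaling. Lce and Sprr2 genes are close paralogs, so reads may be shared within each family; gene length and level were compared only for the ribosomal set, where matched genes had a median of −0.12.

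Tests from here on were chosen after the results were seen. The rise of fibroblast markers with TGFb1+BMP4 was weighed first. A larger share of fibroblasts with an unchanged profile would raise the markers alike, if no other cells express them, which was not tested. Among the 6 markers with at least 10 CPM with the inhibitor, the largest and the smallest change, Col1a1 and Fbln1, lay 7.47 apart. Standard errors were at most 0.36. Under that condition the gap argues against a larger share of fibroblasts as the sole source. The width of the gap rests on Fbln1, the only 1 of the 14 markers to fall. A lower share of epithelial cells would raise the other cell types alike. The 20 immune, endothelial and muscle markers had a median of 0.70 (quartiles 0.20 and 1.14) against quartiles of 1.08 and 4.30 for the fibroblast markers. No minimum CPM was set for the 20, and some lay near the floor, such as Tek with 1 read in the inhibitor group. Adding 1 to CPM pulls the changes of such genes toward 0, and the quartile ranges overlap. The lower median therefore cannot decide on a lower share of epithelial cells. A change of expression within cells, in fibroblasts or in the epithelium, may remain and cannot be placed in either by libraries of whole organoids. Sorted or single cells would test it.

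The fall of ribosomal protein genes with TGFb1+BMP4 was set against their length and composition. A set of 208 other protein-coding genes matched on exon length, GC content and mean expression had a median of −0.12 (quartiles −0.72 and 0.23), above the quartiles of −1.10 and −0.80 of the ribosomal set, which argues against such a bias as the whole of it. A larger share of nuclear RNA might go with the higher Malat1 (0.76) and Neat1 (1.04). Mitochondrially encoded genes, whose RNA also lies outside the nucleus, had a median of −0.11 (quartiles −0.28 and 0.01), which argues against that. Whether growth signalling was lower with the ligands was not tested, and no other technical source was tested.

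The fall of Gli1, Gli2, Ptch1 and Foxe1 with ibuprofen was checked against cell composition and single libraries. Loss of basal keratinocytes or fibroblasts would lower their markers by about as much. These 4 were picked because they fell, while of the other Hedgehog targets 1 rose and 3 did not pass. The smallest change of the 4 was −1.41. The whole list of 8 had a median of −1.20, or −0.62 without TGFb1+BMP4 replicate 2. Basal markers, of which 4 of 14 rose and 1 fell, had a median of −0.009 (quartiles −0.21 and 0.52). The basal markers thus did not fall as a set, though Krt5, which marks the cells given SmoM2, changed by −0.38 (SE 0.11). Fibroblast markers, of which 5 of 14 fell and 1 rose, had a median of −0.416 (quartiles −0.65 and 0.08), and Postn fell by 2.67. Since the 4 genes were picked for falling, their larger falls cannot decide on a loss of basal keratinocytes or of fibroblasts. Without TGFb1+BMP4 replicate 2, the higher library, all 4 genes still fell but by less, at −3.21, −2.51, −2.03 and −0.91. The direction of the falls thus did not rest on that library, while part of their size did. Fewer cells with the active Smoothened cannot be told apart from lower signalling below it, as Smo did not pass (0.13, SE 0.12) but the reads do not separate the transgene from the native gene. An effect of ibuprofen on the pathway downstream of Smoothened may be tested with reads over the SmoM2 mutation or with Hedgehog reporters.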
